A study of Mus musculus with 24 samples.

How the data were processed

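ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open chromatin, was carried out on macrophages grown from the bone marrow of male C57Bl/6 mice. Diabetes had been induced with streptozotocin, a toxin that destroys insulin-producing beta cells, and non-diabetic mice served as controls. Per the labels, the macrophages were left unstimulated or were stimulated with 100 ng/mL lipopolysaccharide (LPS) and 10 ng/mL interferon gamma (IFNγ). The series description states that 6 diabetic and 6 control samples were each divided between both states, so the 24 libraries form 4 groups of 6. Replicate numbers were taken from the sample titles. The labels do not say that a number marks the same mouse in both states, and the comparisons were therefore unpaired. The stimulation time is uncertain, because the treatment protocol gives a culture of 6 h for cells exposed to IL-1β, a stimulus that no other label of these samples names. Per the labels' protocols, nuclei of 50000 cells per replicate were transposed, fragments above 1200 bp were removed, and single reads of 50 bp were sequenced on an Illumina HiSeq instrument.

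The authors deposited 1 peak list per library in the narrowPeak format, called separately for each library. The submitters' processing notes name Trim Galore, FastQC 0.11.3, Bowtie2 2.2.6, MACS2 2.1.1, DiffBind 2.4.8 and edgeR, with the mm10 build. The roles and settings of these tools, and whether reads were shifted for the Tn5 insertion offset, are not given in the sources used here. Each deposited peak carries a score, a fold enrichment over the local background at the summit, and the −log10 p-value and −log10 q-value of the caller. The deposited score was the integer part of 10 times the −log10 q-value in every list. The smallest deposited −log10 q-value was 1.302, a q-value of 0.0499, so the lists end at a q-value of about 0.05. These per-peak values are the authors' own and were used only to describe, rank or filter peaks within a list. A region without a peak was below this calling threshold, which does not show that its chromatin was closed.

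Read totals are not given in the sources used here. In 5000 peaks drawn from each library, the fold and the −log10 p-value were solved together as a whole number of tags and a background level, with a pseudocount of 1 in the fold, to within 0.003 of the −log10 p-value. A solution was found for 100% of these peaks, and for at most 1.98% of a library's peaks once folds and p-values had been shuffled. The lowest background level of each library was also its most frequent. It ranged from 0.664 to 1.007 tags and served as a measure of relative depth.

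Peaks of all 24 lists were merged where they overlapped by at least 1 bp, and regions found in at least 2 libraries were kept. Every region was scored as found or not found in each library. The number of libraries with a peak was compared between groups with a two-sided Fisher's exact test per region. P-values were adjusted with the Benjamini-Hochberg method over the regions whose number of detections could give an unadjusted p under 0.05, at a threshold of 0.05. A region is called gained where it passed and was found in more stimulated libraries, and lost where it passed and was found in fewer. The interaction of phenotype and stimulation was tested per region with Zelen's exact test of equal odds ratios. Values per library (peak number, covered length, median peak width, share of peaks at gene ends, peak density at gene lists) were compared with two-sided exact permutation tests over all 924 label orders of 6 against 6 libraries, whose smallest p is 0.00216. Interactions of these values used every combination of label orders within both states. The region tests were tested on simulated detection data with known changes before use.

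Genes came from a RefSeq table of assembly GRCm38.p6, whose chromosomes are those of mm10. With peak summits in place, 23.6% lay within 1 kb of a gene end, against 5.54% and 5.31% after all genes were moved by either of 2 fixed distances. That table gives gene starts and ends without strand, so 2 planned definitions were changed: a region was assigned to the protein-coding gene body nearest its midpoint, within 50 kb, and a summit within 1 kb of either end of a gene replaced a summit at a promoter. Exons, introns and UTRs were not resolved. The nearest gene need not be the gene a region acts on, which applies most to clustered families such as the Gbp and Cxcl genes. Planned motif tests needed genome sequence and were not run.

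Before the data were examined, 18 gene lists were fixed: 10 pathway lists (inflammatory cytokines, interferon response, classical activation, alternative activation, antigen presentation, negative feedback, lipid handling, glycolysis, trained immunity and diabetes, cell cycle) and 8 marker lists (macrophage identity, neutrophils, T and NK cells, B cells, erythroid and megakaryocytic cells, stromal and endothelial cells, dendritic cells, mast cells and basophils). Of the 339 listed genes, 336 were matched, all but Mx1, Mx2 and Cxcl11. No gene stood in more than 1 list. Peak density is the number of a library's peaks whose summit has a list gene as its nearest gene within 50 kb, per 1000 peaks of that library, adjusted over the 18 lists of each contrast. The rule for named regions, all within 50 kb of a gene and each gene once, was fixed at the same time: the 10 gained and 10 lost regions with the largest difference in libraries, ties broken by the highest mean within-list percentile of the −log10 q-value. Where no region passed, the rule took the 5 with the smallest p in each direction. From each list it took up to 4 genes with the most called regions, and every gene in a group of 5 or fewer that the text counts. Results for some genes that this rule takes are not reported here.

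The alternative settings chosen beforehand were lists of equal length (the 41385 peaks of each library with the highest −log10 q-value, the length of the shortest list), a stricter threshold (−log10 q-value of at least 5), windows of 501 bp around summits, regions found in at least 4 libraries, adjustment over all regions, a replicate block, gene ends within 2.5 kb and list genes within 10 kb. Leaving out each library in turn, list counts at equal length and the median fold over regions found in every library were added after the data had been seen. Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.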

Results

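Chromatin accessibility was profiled by ATAC-seq in bone marrow-derived macrophages of streptozotocin-diabetic and non-diabetic control mice, before and after stimulation with LPS and IFNγ, a pair of signals that drives classical (inflammatory) macrophage activation. There were 6 libraries per group. The peak lists held between 41385 and 61861 peaks per library and 1274891 in all. Mean peak numbers were 55990 ± 3486 in unstimulated control, 55522 ± 4925 in unstimulated diabetic, 47268 ± 4535 in stimulated control and 53703 ± 4511 in stimulated diabetic macrophages (SD, n = 6 each). Merging gave 80598 regions with a median width of 417 bp, of which 22770 (28.3%) were found in all 24 libraries and 88.1% lay within 50 kb of a protein-coding gene body. Stimulation separated the libraries along the first principal component of region detection, which held 19.3% of the variance, with every unstimulated library on one side and every stimulated library on the other. The median share of regions held in common by a pair of libraries (Jaccard index) was 63.4% across states, 71.2% between phenotypes within a state and 72.2% within a group.

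**Figure D1:**
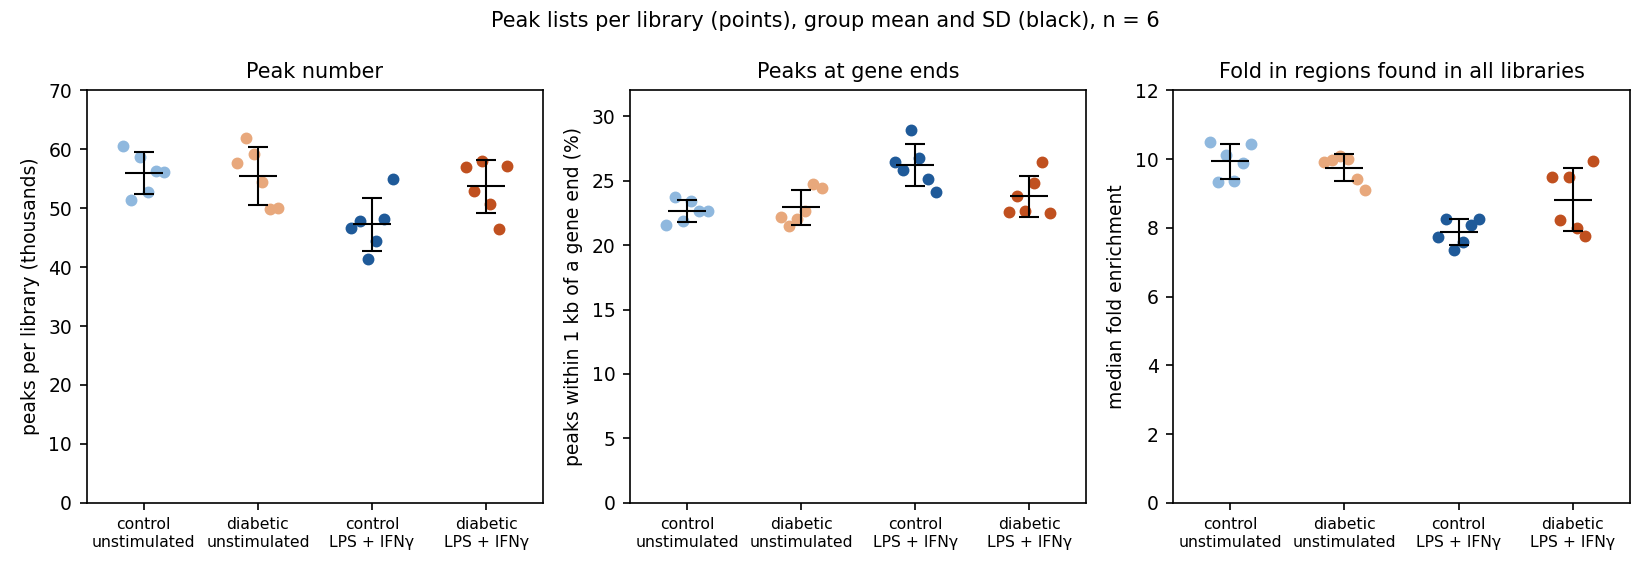
Number of peaks per library (axis in units of 1000 peaks), percent of peaks with a summit within 1 kb of a gene end, and median fold enrichment over the 22770 regions found in all libraries; points are libraries, black lines the group mean and SD (n = 6). Stimulated control libraries had the fewest peaks (mean 47268), the highest share at gene ends (26.2%) and the lowest median fold (7.88).

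The first question was which regions open or close when these macrophages meet LPS and IFNγ, with phenotypes pooled (12 against 12 libraries). Interferon response genes had more gained than lost regions (23 and 8), with gains at Usp18 and Ifit2, whereas genes of alternative activation (3 gained and 17 lost, with losses at Irf4) and of lipid handling (4 and 16, with losses at Cd36 and Lpl) had more lost ones. Genes of classical activation went both ways (16 and 14), with gains at Nos2 and Il15. Over all tested regions, 67.3% of calls were losses, so more losses than gains near a list are not by themselves particular to it. The balance of no list was tested against this share. Gained regions numbered 2868 and lost regions 5901 of 31219 tested. Of these, 233 gained regions were found in all 12 stimulated and no unstimulated libraries, and 141 lost regions showed the opposite pattern. Fisher's exact test gave these complete separations an adjusted p of 6.174e-05. Lists of equal length gave 3170 gained and 3838 lost regions, and the share of called regions that were lost went from 67.3% to 54.8%. The regions passing under both settings were 1950 of the 2868 gained and 2672 of the 5901 lost.

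The most prominent gained region lay within Nfkb1, which encodes an NF-κB subunit (chromosome 3, 135640137 to 135640654, mm10). It was found in 12 of 12 stimulated and 0 of 12 unstimulated libraries. The other 9 of the leading gained regions had the same counts. Within gene bodies, these were at the ubiquitin-conjugating enzyme gene Ube2z (chromosome 11, 96058253 to 96058859), the deubiquitinase gene Usp47 (chromosome 7, 112053362 to 112054173) and Dapp1, which encodes an adaptor of phosphoinositide signalling (chromosome 3, 137965876 to 137966335). Outside gene bodies, they lay 12909 bp from Tnfsf15, a member of the tumour necrosis factor ligand family (chromosome 4, 63757686 to 63758251), and 23772 bp from the formyl peptide receptor gene Fpr2 (chromosome 17, 17917413 to 17918036). The remaining 4 lay 18253 bp from Cdk20, 31708 bp from the glutamate receptor gene Grm5, 41825 bp from Phip, and 47566 bp from Id2, an inhibitor of basic helix-loop-helix factors.

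The leading lost regions were found in 12 of 12 unstimulated and 0 of 12 stimulated libraries. Gene bodies held 8 of these 10, at Hpgd, which encodes a prostaglandin-degrading dehydrogenase (chromosome 8, 56313645 to 56314002), the heparan sulfate proteoglycan gene Sdc4 (chromosome 2, 164441144 to 164441588), the unconventional myosin gene Myo10 (chromosome 15, 25764622 to 25765149) and Pik3r1, which encodes a regulatory subunit of phosphoinositide 3-kinase (chromosome 13, 101760284 to 101760666), as well as Slc17a5, Lyst, Fnip2 and Celf6. Slc17a5 and Lyst act in lysosomes, as the sialic acid exporter and a regulator of lysosomal trafficking. The other 2 lay 9566 bp from Btbd8 and 14143 bp from the amino acid transporter gene Slc7a13. All 20 leading regions also passed with lists of equal length. Ties were broken by high −log10 q-values, by which equal lengths also keep peaks, so this outcome was nearly fixed by the selection.

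The interferon response list moved mostly towards gain, with 23 gained and 8 lost among 54 tested regions, and 24 gained and 10 lost when adjusted over the list alone. Of its 32 matched genes, 13 had only gained regions, 5 (Gbp2, Ifi47, Ifih1, Irf1, Rsad2) had both kinds, Gbp3 had only a lost region, and 13 had no called region. A region within Usp18, the gene of a feedback protease of interferon signalling (chromosome 6, 121250021 to 121250532), and 1 region 836 bp from the guanylate-binding protein gene Gbp2 (chromosome 3, 142638364 to 142639324) appeared in 12 of 12 stimulated and 0 of 12 unstimulated libraries. Ifit2 gained 3 regions. Regions at Cxcl9 and Cxcl10, chemokines that attract T cells, were found in 11 stimulated and 0 unstimulated libraries (adjusted p = 0.000303). With lists of equal length this group had 24 gained and 4 lost regions.

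Inflammatory cytokine genes had 10 gained and 6 lost of 48 tested regions, the same counts when adjusted over the list alone. Of 22 genes, 5 (Ccl4, Ccl5, Il12a, Il6, Ptges) only gained regions, 3 (Cxcl1, Cxcl3, Lif) only lost them, 3 (Cxcl5, Il12b, Il1b) did both and 11 had no call. The gained Il12b region lay 17709 bp from the gene, which encodes an interleukin subunit made by activated macrophages, and was found in 12 against 0 libraries (chromosome 11, 44382099 to 44382610). At Il1b, the gene of interleukin 1 beta, a region 4132 bp away went the other way, from 12 unstimulated to 3 stimulated libraries (adjusted p = 0.00388).

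Genes of classical activation had 16 gained and 14 lost of 64 tested regions, also when adjusted over the list alone. Only gains occurred at 6 of 23 genes, only losses at 2 (Marco, Saa3), both at 5 (Acod1, Cd40, Cd80, Cd86, Slamf7) and neither at 10. Nos2, the inducible nitric oxide synthase gene, gained a region 31544 bp away that was found in 12 against 0 libraries (chromosome 11, 78889034 to 78889453), and Il15 and its receptor gene Il15ra each gained an intragenic region with the same counts. Il15 gained 3 regions in total. Acod1, which encodes the enzyme that makes itaconate, gained a region 374 bp beyond the gene, found in 11 against 0 libraries, and lost 2 within it. The costimulatory gene Cd86 gained 2 regions and lost 5.

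Genes of alternative activation had 3 gained and 17 lost of 54 tested regions, also when adjusted over the list alone. Losses made up 67.3% of calls over all regions, a share this balance was not tested against. Only losses occurred at 6 of 20 genes, only a gain at Egr2, both at Mrc1 and Ppargc1b, and neither at 11. The mannose receptor gene Mrc1 lost 5 regions and gained 1. Its most separated lost region (chromosome 2, 14269233 to 14269589) was found in 11 unstimulated and 0 stimulated libraries (adjusted p = 0.000303). Pparg, the gene of a lipid-sensing nuclear receptor, lost 3 regions, of which 1 passed with lists of equal length, and Irf4 lost 2, both passing there. With lists of equal length the group had 4 gained and 17 lost regions.

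Lipid-handling genes had 4 gained and 16 lost of 52 tested regions, also when adjusted over the list alone. Regions were only lost at 10 of 25 genes, both gained and lost at Msr1, and not called at 12. Lists of equal length gave 5 gained regions, at 2 genes, and 11 lost regions, at 5 genes, and no region at Msr1 passed. The fatty acid and lipoprotein scavenger receptor gene Cd36 lost 3 intragenic regions. One of these (chromosome 5, 17849609 to 17849933) went from 12 unstimulated to 0 stimulated libraries. The lipoprotein lipase gene Lpl and the cholesterol exporter gene Abca1 also lost regions, whereas Ch25h, which encodes a cholesterol hydroxylase induced by interferon, gained 2. Macrophage identity genes, used as markers of the cells themselves, had 4 gained and 16 lost of 58 tested regions, and 6 and 11 with lists of equal length. With all peaks, Irf8 and Mitf showed both directions and 8 genes, among them Gpnmb with 4 regions and Cd14 with 2, only losses. A region 24969 bp from Irf8, the gene of a transcription factor of the myeloid lineage, went from 0 to 12 libraries, as did 1 within Mitf.

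**Figure D2:**
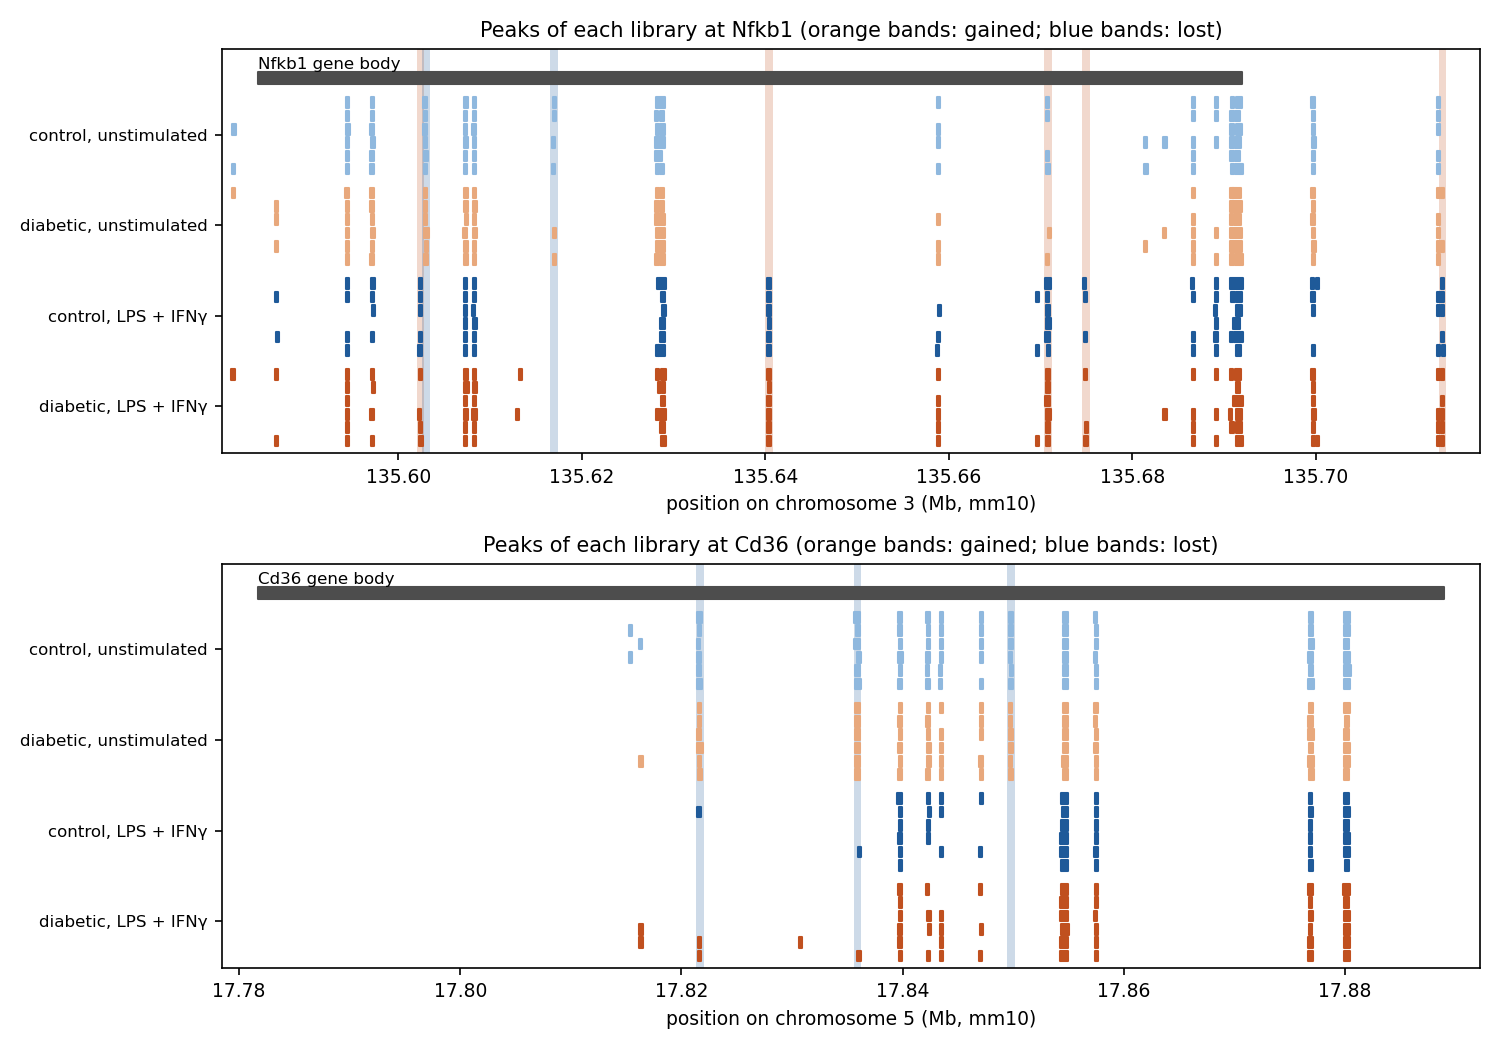
Positions of the peaks of each library (coloured bars, 1 row per library, 6 rows per group) along the genes Nfkb1 on chromosome 3 and Cd36 on chromosome 5 (mm10, Mb), with regions gained after stimulation shaded orange and regions lost shaded blue. The Nfkb1 region starting at 135640137 was found in 12 stimulated and 0 unstimulated libraries, and the Cd36 region starting at 17849609 in 12 unstimulated and 0 stimulated libraries.

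Negative feedback genes moved in both directions, with 13 gained and 20 lost of 74 tested regions, also when adjusted over the list alone. Gains without losses occurred at Cish, Il1rn, Socs1 and Tnip1, losses without gains at Dusp1, Nfkbia, Socs3 and Tnip3, and both at Irak3, Nfkb1, Nfkbiz and Tnfaip3, with 8 of 20 genes uncalled. Nfkb1 gained 5 regions and lost 2, and Tnip3 lost 5. Tnfaip3, which encodes the ubiquitin-editing inhibitor of NF-κB signalling, lost an intragenic region found in 12 unstimulated and 0 stimulated libraries and gained another found in 11 stimulated and 1 unstimulated library. The trained immunity and diabetes list had 8 gained and 15 lost of 81 tested regions, also when adjusted over the list alone, but 7 and 8 with lists of equal length. Gains alone occurred at Insr, Irs2, Kmt2a and Nod2, both directions at Igf1r, Il6ra and Runx2, losses alone at 6 genes including Tlr2 and Runx1, and no call at 10 of 23. The pattern recognition receptor gene Nod2 gained a region found in 12 stimulated and 1 unstimulated library (adjusted p = 0.000303), and Tlr2 lost 1 found in 11 unstimulated and 0 stimulated libraries.

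The smaller groups held fewer calls. Antigen presentation genes had 2 gained and 7 lost of 25 tested regions, with a gain at Ciita, the activator of MHC class II genes, losses at B2m, Cd74 and Psmb9, and both at Nlrc5, and with lists of equal length the balance turned to 4 gained and 2 lost. Glycolysis genes had 3 gained and 6 lost of 43 tested regions (3 and 4 when adjusted over the list alone, 6 and 9 with lists of equal length), with a gain at Hif1a, losses at Eno1, Hk1, Ldha and Pfkl and both at Pfkfb3 and Slc2a1. Cell cycle genes had 2 gained (Ccne1, E2f8) and 4 lost regions (Ccnd1, Ccnd2 and 2 at Mki67) of 30 tested, and 5 of each with lists of equal length. Markers of other bone marrow cells were called as follows. Neutrophil genes gained 4 regions (Ltf, Mmp8, Mmp9) and lost 3 (Cebpe, Fcnb, Mpo). T and NK cell genes lost 5 (Cd2, Cd28, Cd4, Themis). Dendritic cell genes gained 1 (Ccr7) and lost 5 (Batf3, Bst1, Ccr7, Flt3). Stromal and endothelial genes gained 3 (Dcn) and lost 2 (Cdh5, Pecam1). An erythroid region was lost (Slc4a1), a mast cell region was gained (Kit), and no B cell region was called. Adjusted over the list alone, T and NK cell genes lost 4 regions, stromal and endothelial genes gained 2 and no mast cell region passed. With lists of equal length, T and NK cell genes lost 3 regions, dendritic cell genes gained 2 and lost 2, stromal and endothelial genes gained 2 and lost 1, and no erythroid region was called. Over all lists, 71 of 97 gained and 79 of 145 lost regions also passed with lists of equal length. Of the list genes named here, B2m, Bst1, Ccnd1, Ccr7, Cd28, Cdh5, Ciita, Cxcl3, Cxcl5, Flt3, Il1rn, Kmt2a, Mmp9, Mpo, Msr1, Pecam1, Pfkfb3, Psmb9, Runx1, Slc4a1, Socs1 and Themis kept no call there. Among genes called in both directions, the gains at Il1b, Irf1, Nfkbiz and Slc2a1 and the losses at Ifi47, Ifih1, Igf1r, Il12b, Il6ra and Rsad2 did not pass there. At Nfkb1, 4 of 5 gained and 1 of 2 lost regions passed there, and at Cd86 1 of 2 gained and 4 of 5 lost. Of the lost regions, 3 of 5 passed there at Tnip3, 2 of 4 at Gpnmb, and 1 of 2 at both Cd14 and Acod1. Of the gained regions, 1 of 2 passed there at Ch25h and 1 of 3 at Dcn.

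**Figure D3:**
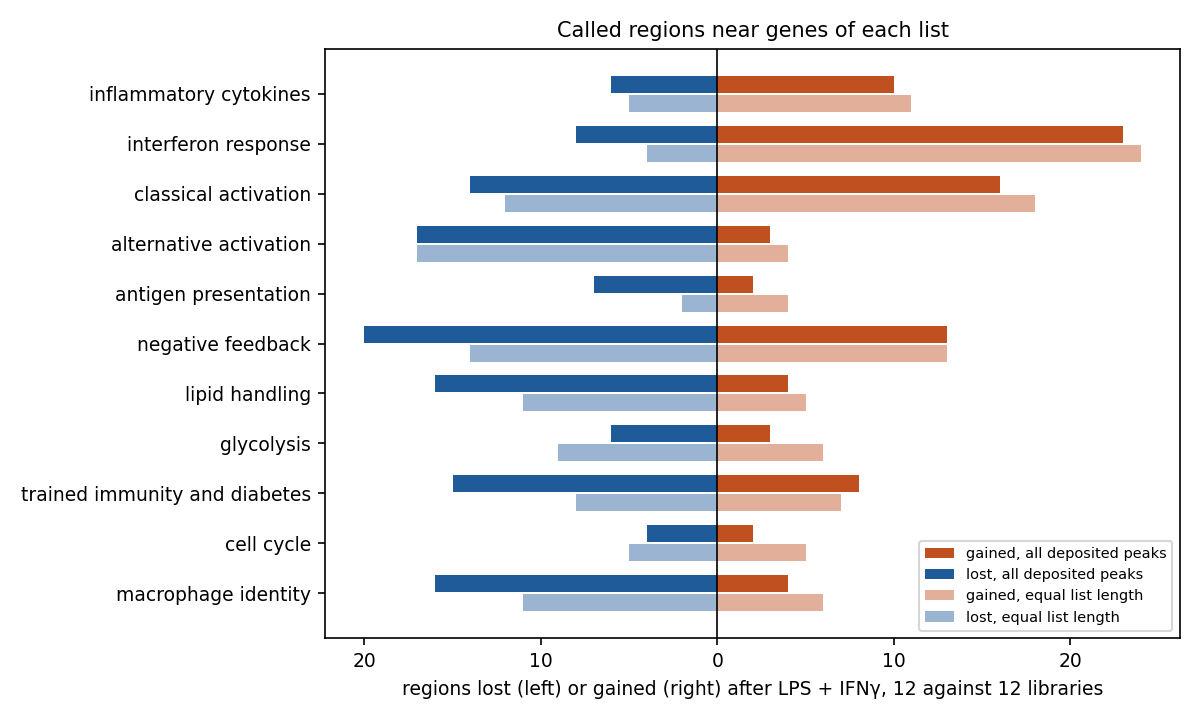
Regions gained (right) and lost (left) after stimulation near the genes of 11 lists, with all deposited peaks (dark bars) and with lists of equal length (pale bars), 12 against 12 libraries. The interferon response list had 23 gained and 8 lost regions with all peaks, and the alternative activation list 3 gained and 17 lost. Over all regions, 67.3% of calls were losses with all peaks.

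In control macrophages alone, interferon and cytokine genes held a larger share of the peaks after stimulation. The mean peak number fell from 55990 to 47268, so a higher density per 1000 peaks does not by itself mean more peaks near a list. Peak density at interferon response genes rose from 1.33 ± 0.0255 to 1.81 ± 0.098 peaks per 1000 (SD, n = 6, ratio 1.37, exact permutation p = 0.00216, adjusted p = 0.0195), and at inflammatory cytokine genes from 1.40 ± 0.0487 to 1.76 ± 0.11 (ratio 1.26, adjusted p = 0.0195). In both lists all 6 stimulated libraries lay above every unstimulated one. Density at classical activation genes rose 1.12-fold (adjusted p = 0.026), which did not pass with lists of equal length (adjusted p = 0.108). No other list passed with all peaks. With lists of equal length, density at alternative activation genes (adjusted p = 0.013) and lipid-handling genes (adjusted p = 0.0195) was lower in stimulated control macrophages and that at erythroid and megakaryocytic genes higher (adjusted p = 0.0234). The share of peaks at gene ends rose from 22.6% ± 0.854 to 26.2% ± 1.64 (SD, n = 6, exact permutation p = 0.00216, adjusted p = 0.0346), and with lists of equal length from 25.665% to 27.65%.

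Region by region, 1018 gained and 3331 lost regions were called in control macrophages of 12111 tested, and with lists of equal length 1471 and 1775. Interferon response genes accounted for 13 gained and 9 lost regions, classical activation genes for 10 and 7, inflammatory cytokine genes for 4 and 3, and alternative activation genes for 2 and 10, also when adjusted over the list alone. Complete separation (6 against 0 libraries) was seen in 441 gained and 1078 lost regions, where 9.64 were expected by chance among the regions found in 6 of 12 libraries (a chance share of 0.216%). Beyond the regions leading the pooled comparison, the named regions were those at Atg4c and Tnfrsf8 (gained) and Apaf1, Olfr694, Dlgap1 and Rere (lost). Peak number was 15.6% lower in stimulated than in unstimulated control libraries (exact permutation p = 0.00649, adjusted p = 0.0519, not passing). The median fold over regions found in every library was 7.88 ± 0.375 against 9.94 ± 0.504 (SD, n = 6, exact permutation p = 0.00216, a measure added after the data had been seen). In diabetic macrophages this fold was also lower after stimulation, 8.82 ± 0.92 against 9.75 ± 0.394 (SD, n = 6, exact permutation p = 0.0584). In control macrophages, no region passed when all 80598 regions entered the adjustment, 638 were gained with peaks at a −log10 q-value of at least 5, and leaving out any of 9 libraries lowered the counts to between 466 and 544 gained and between 1149 and 1325 lost.

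In diabetic macrophages, stimulation raised peak density at the same 3 lists. It rose from 1.28 ± 0.0781 to 1.70 ± 0.126 peaks per 1000 at interferon response genes (SD, n = 6, ratio 1.33, exact permutation p = 0.00216, adjusted p = 0.013), from 1.47 ± 0.066 to 1.68 ± 0.076 at inflammatory cytokine genes (ratio 1.15, adjusted p = 0.013) and from 1.70 ± 0.0721 to 1.92 ± 0.0908 at classical activation genes (ratio 1.13, adjusted p = 0.013). All 6 stimulated libraries lay above every unstimulated one in each of these lists. The classical activation list did not pass with lists of equal length (adjusted p = 0.0557). There, alternative activation, lipid-handling and macrophage identity genes had lower density after stimulation (adjusted p = 0.039, 0.0195 and 0.039) and antigen presentation genes higher density (adjusted p = 0.039).

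**Figure D4:**
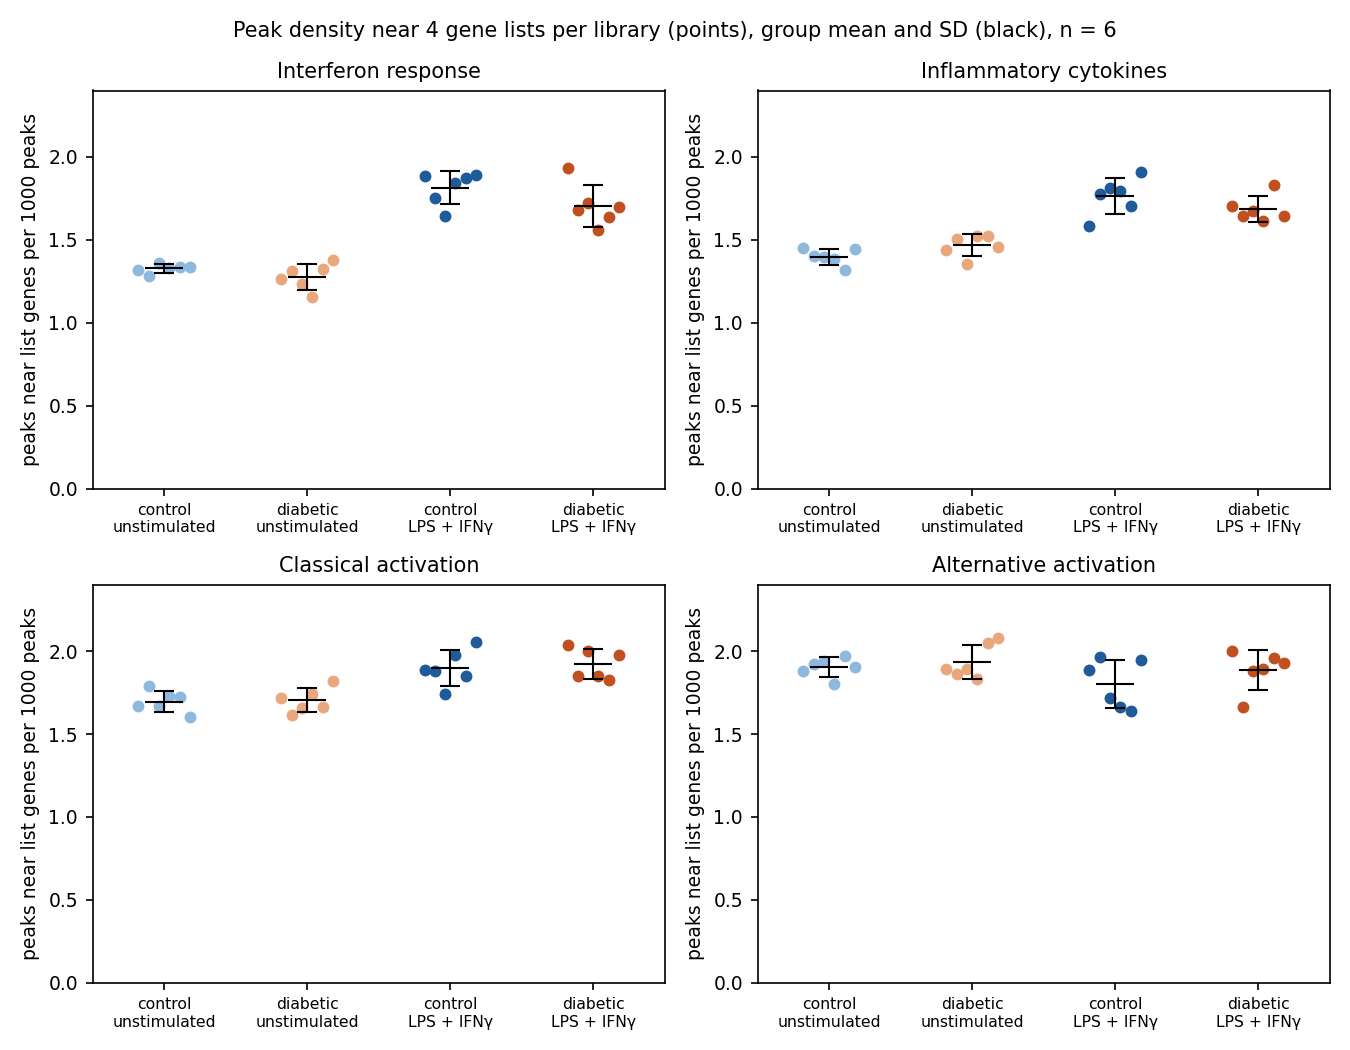
Peaks per 1000 with a summit nearest to a gene of the interferon response, inflammatory cytokine, classical activation and alternative activation lists; points are libraries, black lines the group mean and SD (n = 6). Density at interferon response genes rose from 1.33 to 1.81 in control and from 1.28 to 1.70 in diabetic macrophages.

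By region, 641 gained and 403 lost regions were called in diabetic macrophages of 11708 tested, each of them a complete separation, where 8.96 were expected by chance. With lists of equal length 1580 were gained and 1304 lost. Interferon response genes held 9 gained and 0 lost regions, classical activation genes 6 and 0, inflammatory cytokine genes 3 and 0, and negative feedback genes 6 and 4. Adjusted over the list alone, these counts were 15 and 3, 10 and 3, 6 and 2, and 7 and 9, so the balance of the negative feedback genes turned. Named regions outside those of the pooled comparison were at Ikzf5 (gained) and at Hint1 and 4930486L24Rik (lost). The call in diabetic macrophages needed complete separation whereas that in control macrophages also took regions at an exact p of 0.0152, so the counts of the phenotypes do not measure the size of the response, and no region passed when all 80598 entered the adjustment. Leaving out stimulated diabetic replicate 5 raised the gained regions to 1010, and with peaks at a −log10 q-value of at least 5 the balance turned to 373 gained and 380 lost.

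The responses of both phenotypes pointed the same way. Among 5650 regions tested in both, 387 were gained in both against 60.1 expected from independent lists, and 256 were lost in both against 82.0 expected. No region was called in opposite directions. The phenotypes shared no libraries in these tests. Regions at Nfkb1, Fpr2, Tnfsf15, Hpgd, Sdc4 and Myo10 were among those called in both, with 6 against 0 libraries in each phenotype. These regions led the pooled comparison by complete separation, which fixes their counts in each phenotype.

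The central question of the series was whether macrophages of diabetic mice differ from those of control mice before any stimulus. No region passed the test among 8788 tested, and density differed at none of the 18 gene lists after adjustment. The regions with the smallest p were found in all 6 diabetic and no control libraries at Spata13, Sp7 and Fbxo28, and in all 6 control and no diabetic libraries at Add3, Fgd6 and Zfp362 (Fisher's exact p = 0.00216, adjusted p = 0.972). Another region with the latter counts, named after its values had been seen, lay 63128 bp from its nearest gene, Rnf19a (chromosome 15, 36346124 to 36346426). At Irak4, the gene of a kinase that relays Toll-like receptor signals, a region (chromosome 15, 94564864 to 94565301) was found in 6 control and 1 diabetic unstimulated library and in all 12 stimulated libraries (Fisher's exact p = 0.0152, adjusted p = 0.972). Extl3 and Mogat2 (higher in diabetic) and Cartpt (lower) completed the named regions, none of which passed.

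Density at trained immunity and diabetes genes was 2.77 ± 0.14 peaks per 1000 in diabetic and 2.61 ± 0.134 in control macrophages (SD, n = 6, exact permutation p = 0.0693, adjusted p = 0.312). Among the marker lists, that of neutrophils was at 0.433 ± 0.0515 against 0.367 ± 0.0407 (exact permutation p = 0.0346) and that of T and NK cells at 0.538 ± 0.0465 against 0.473 ± 0.0489 (exact permutation p = 0.039), both with an adjusted p of 0.312. Within the trained immunity list the most unequal regions lay at Il6ra and Tlr4, each found in 5 diabetic and 1 control library (Fisher's exact p = 0.0801). Peak number (55522 and 55990), median peak width (298 and 296 bp) and the share of peaks at gene ends (22.9% and 22.6%) differed by less than the spread between replicates. At an unadjusted p under 0.05, Fisher's exact test gave 58 regions higher and 79 lower in diabetic macrophages, a balance that turned without unstimulated diabetic replicate 4 (138 and 129), 5 (159 and 100) or 6 (157 and 117), and 3 and 4 regions separated the groups completely where 6.15 were expected by chance and 381 would have been needed for a call. In simulated data with 2000 changed regions, 54.8% of those moved from a detection rate of 0.05 to 0.95 or back and 3.1% of those moved between 0.25 and 0.75 were recovered, and none with 200 changed regions.

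The same comparison after LPS and IFNγ asked whether diabetic macrophages respond from or towards a different chromatin state. No region passed among 9681 tested, and no gene list differed in density after adjustment. The leading regions were found in all 6 diabetic and no control stimulated libraries, with a Fisher's exact p of 0.00216 and an adjusted p of 0.502. Those at Mctp1, Zmynd10, Ccdc148 and Gm14037 were also found in all 12 unstimulated libraries. The region within Inpp4b, which encodes a phosphoinositide phosphatase (chromosome 8, 81636127 to 81636811), was found in the 6 stimulated diabetic libraries and in none of the other 18. In the other direction, a region within Acod1, the itaconate synthase gene (chromosome 14, 103052327 to 103052904), was found in 5 of 6 stimulated control libraries and in no diabetic or unstimulated library (Fisher's exact p = 0.0152, adjusted p = 0.502).

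Mast cell and basophil genes had 0.195 ± 0.02 peaks per 1000 in diabetic and 0.142 ± 0.051 in control macrophages (SD, n = 6, exact permutation p = 0.0498, adjusted p = 0.529). Rragd, Nr6a1, Cdc42se2 and F2rl1 held the other regions found in fewer diabetic libraries, each with a difference of 5 libraries and none passing. Density at interferon response genes was 1.70 ± 0.126 peaks per 1000 in diabetic and 1.81 ± 0.098 in control macrophages (SD, n = 6, exact permutation p = 0.13, adjusted p = 0.529), and at trained immunity and diabetes genes 2.65 ± 0.146 and 2.66 ± 0.192 (exact permutation p = 0.883, adjusted p = 0.885). In that list a region 40217 bp from Irs2, which encodes an insulin receptor substrate, was found in 6 diabetic and 1 control library (Fisher's exact p = 0.0152, adjusted p = 0.502). Stimulated diabetic libraries had 13.6% more peaks than stimulated control libraries (exact permutation p = 0.0346, adjusted p = 0.139) and a median fold over regions found in every library of 8.82 ± 0.92 against 7.88 ± 0.375 (SD, n = 6, exact permutation p = 0.0606). Diabetic replicates 1, 3 and 6 carried most of this, with 56932, 58016 and 57100 peaks and folds of 9.48, 9.47 and 9.94, whereas the folds of replicates 2, 4 and 5 (7.77 to 8.24) lay within the control range of 7.35 to 8.26. At an unadjusted p under 0.05, Fisher's exact test gave 283 regions higher and 9 lower in diabetic macrophages, 92 and 52 with lists of equal length, and between 358 and 722 higher and between 12 and 31 lower without any 1 library. Complete separation was seen in 26 regions, all higher in diabetic, where 6.89 were expected by chance and 420 would have been needed for a call. In simulated data with 2000 changed regions, 54.0% of those moved from a detection rate of 0.05 to 0.95 or back and 3% of those moved between 0.25 and 0.75 were recovered, and none with 200.

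Whether the response to stimulation itself differed between phenotypes was tested as the interaction of both factors. No region passed among 9353 tested. The leading regions lay at or near Uckl1, Spata1, Ripor2, H2-M10.4 and Ywhab, where detection fell with stimulation in control and rose in diabetic macrophages, and at Pkhd1l1, Glrx5, Hapln1, Cdc42se2 and F2rl1, where the response of diabetic macrophages was the lower one. At Uckl1, a region 719 bp from the gene (chromosome 2, 181568227 to 181568634) went from 5 to 0 libraries in control and from 0 to 5 in diabetic macrophages (Zelen's exact p = 0.000367, adjusted p = 1). The response of peak density, diabetic minus control, was −0.147 peaks per 1000 at inflammatory cytokine genes (exact permutation p = 0.0292) and −0.177 at glycolysis genes (exact permutation p = 0.0432), neither passing over the 18 lists (adjusted p = 0.389 for both). Density at glycolysis genes went from 1.736 to 1.834 in control and from 1.803 to 1.724 in diabetic macrophages. The gain in the share of peaks at gene ends differed by −2.70 percentage points (exact permutation p = 0.035, adjusted p = 0.14) and by −1.34 with lists of equal length (unadjusted exact permutation p = 0.0342), and that in peak number by 6903 peaks (exact permutation p = 0.0792, adjusted p = 0.158). The median fold over regions found in every library differed in its response by 1.14 (exact permutation p = 0.0344). Zelen's test gave 229 regions at an unadjusted p under 0.05, of which 200 were higher and 29 lower in the diabetic response, and 89 and 58 with lists of equal length.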

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

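Tests of explanations, counts over other splits of the libraries and the median fold over shared regions were chosen after the results they bear on had been seen. Among 92 groups of 6 libraries examined for a single value far from the rest, 8 held one, where chance gives about 1 in 20, or 4.6.

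Each of these values is compared with the other 5 libraries of its own group. Among unstimulated control libraries, replicate 6 had the lowest background tag level (0.664, nearest other 0.803). Among stimulated diabetic libraries, replicate 2 had the fewest peaks per 1000 near alternative activation genes (1.66, nearest other 1.88), and replicate 4 near negative feedback genes (2.21, nearest other 2.56). Among stimulated control libraries, replicate 6 had the most near antigen presentation genes (1.02, nearest other 0.75) and near trained immunity and diabetes genes (3.04, nearest other 2.67). In the unstimulated control group, replicate 1 was highest near antigen presentation genes (0.742, nearest other 0.658), replicate 4 lowest near lipid-handling genes (2.05, nearest other 2.12) and replicate 5 lowest near glycolysis genes (1.6, nearest other 1.73).

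Of 22 values tested for a different response to stimulation in diabetic and control macrophages, 3 differed before adjustment and none after it. The response in diabetic minus that in control macrophages was −2.7 percentage points for the share of peaks at gene ends (exact permutation p = 0.035, adjusted p = 0.14), −0.147 peaks per 1000 near inflammatory cytokine genes (exact permutation p = 0.0292, adjusted p = 0.389) and −0.177 near glycolysis genes (exact permutation p = 0.0432, adjusted p = 0.389).

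In control macrophages, far more regions were lost than gained after stimulation. The background tag level gave no sign of fewer sequenced tags in the stimulated libraries. It was 7.66% higher there (permutation interval −5 to 22%), whereas the peak number was 15.6% lower. The interval includes somewhat fewer tags, and how peak number scales with tags was not measured, so a part played by depth is not excluded. Lower enrichment of the stimulated libraries is a candidate explanation for the excess of losses, since over regions found in all 24 libraries their median fold differed by −20.8% (exact permutation p = 0.00216), with each stimulated library below each unstimulated one. Lists of equal length gave 1471 gained and 1775 lost regions, although equal lengths by construction leave little room for an excess. A true spread of small losses after LPS and IFNγ would lower the same fold and stays open.

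In stimulated macrophages, the regions that separated the phenotypes before adjustment lay mostly on the diabetic side. More sequenced tags in the diabetic libraries could not be excluded: the background tag level differed by −1.51% (permutation interval −16 to 15%) against 13.6% more peaks. Higher enrichment of the diabetic libraries may contribute, but the median fold over regions found in all 24 libraries was 12% higher with an exact permutation p of 0.0606, which 6 libraries per group leave undecided. The higher folds were those of diabetic replicates 1, 3 and 6 (9.47 to 9.94), while replicates 2, 4 and 5 lay within the control range. Neither can be told apart from an effect of diabetes itself, which stays open and untested.

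The real phenotypes were also compared with other groupings of the same libraries. In stimulated macrophages 292 regions stood at an unadjusted p under 0.05, and 3 of 100 splits gave as many (highest other 367). With lists of equal length there were 144, and 4 of 100 splits gave as many (highest other 172). Both shares were under 0.05, but other splits gave more regions than the real one and 8 such counts were made, so chance is not taken as excluded. In unstimulated macrophages the count was 137, and 7 of 100 splits gave as many (highest other 239), and with lists of equal length it was 129 and 1 of 100 splits, the real one, gave as many (highest other 123). The settings thus differed, and chance could not be excluded there either. For the interaction 229 regions stood at an unadjusted p under 0.05, and 7 of 100 relabellings gave as many (highest other 502), so chance could not be excluded.

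For the response to stimulation, called regions were counted in place of regions at an unadjusted p under 0.05, so these counts are not like those between phenotypes. The real groups gave 8769 called regions with phenotypes pooled, 1044 in diabetic and 4349 in control macrophages. In each case 1 of 100 splits, the real one, gave as many, and the highest other count was 0, so chance is an unlikely source of the response. Within a phenotype a count of 0 is easily reached. Calls from complete separation alone needed 507 such regions in diabetic and 525 in control macrophages.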

How the results depend on the processing

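Leaving out single libraries was chosen after the data had been seen. No alternative gave a passing region between phenotypes, and lost regions outnumbered gained ones, pooled and in control macrophages, wherever any were called. In diabetic macrophages gained regions led wherever any were called, except under the stricter threshold, where 380 were lost. Adjustment over all regions left 1706 gained and 2974 lost regions with phenotypes pooled and 0 gained and 0 lost within either phenotype, since too few regions separated 6 against 6 libraries completely for an adjustment over 80598. Lists of equal length gave 3838 lost regions pooled, 1580 gained and 1304 lost in diabetic and 1775 lost in control macrophages, and the stricter threshold gave 373 gained in diabetic and 638 gained in control macrophages. Between stimulated phenotypes, neither peak number nor the share at gene ends passed after adjustment with all peaks (adjusted p = 0.139 for both), and their unadjusted exact permutation p went from 0.0346 to 0.0866 under the stricter threshold and from 0.026 to 0.0584 with equal lengths, while median width differed in control macrophages under the stricter threshold (p = 0.00216). Lists lower in density went from 0 to 3 in diabetic and 2 in control macrophages with equal lengths, and to 1 in control macrophages with genes within 10 kb. The cause of these shifts was not tested. Summit windows moved no count of called regions by over 1.5 times, with 2394 gained and 4639 lost regions pooled. Gene ends within 2.5 kb left the same comparisons at an unadjusted exact permutation p under 0.05. Requiring at least 4 libraries could not change a call. Regions in fewer libraries cannot reach an unadjusted p under 0.05, so they were never among those tested. At an unadjusted p under 0.05, the 9 regions lower in diabetic among stimulated libraries became 20 with summit windows and 4 under the stricter threshold, and the 29 lower in the interaction became 15 under the stricter threshold. Whether replicate numbers pair the libraries of both states could not be decided. Between states of a phenotype, same-number correlations of deviations lay between −0.0098 and 0.0159. Those of other numbers reached 0.0211, and in each phenotype 1 of 6 libraries correlated best with its own number. With correlations this small for all pairs, the check could hardly have detected a shared mouse. The replicate block gave 2222 gained and 4381 lost regions pooled. Within a phenotype it can call only complete separations of 6 against 6 libraries. Its 441 gained and 1078 lost regions in control macrophages therefore say nothing about pairing. It gave 0 lists higher in either phenotype because 64 sign flips cannot pass over 18 lists unless many tie. Between stimulated phenotypes, the exact sign-flip p was 0.0625 for both peak number and the share at gene ends. There the block joined diabetic and control libraries of equal number, which come from different mice, so this p respects no known pairing. Without single libraries, gained regions ranged from 2323 to 3433 and lost ones from 4656 to 7120 pooled, from 666 to 1010 (without stimulated diabetic replicate 5) and from 434 to 587 in diabetic macrophages, and from 466 to 1180 and from 1149 to 4452 in control macrophages. There, the values without unstimulated control replicates 1, 3, 4, 5 and 6 were 504, 484, 470, 466 and 475 gained and 1149, 1186, 1325, 1229 and 1209 lost, and without stimulated control replicates 1, 2, 3 and 4 they were 504, 475, 544 and 520 gained and 1249, 1262, 1163 and 1200 lost, because the call then needed complete separation. Comparisons of phenotypes stayed at 0 called regions without any 1 library. Their counts at an unadjusted p under 0.05 rose in all 24 cases, in part because with 5 against 6 libraries more regions can reach that p (at least 12832 against 8788 unstimulated and 14249 against 9681 stimulated). Unstimulated, they went from 58 higher to between 78 and 159 and from 79 lower to between 100 and 183, over 1.5 times for the higher count without each library but diabetic replicate 2 and for the lower count without each but diabetic replicates 5 and 6. Stimulated, 283 higher became 722, 562 and 494 without diabetic replicates 5, 4 and 2, and 647, 471 and 461 without control replicates 6, 5 and 2, and 9 lower became between 12 and 31 (over 1.5 times without each library but control replicate 6), with higher ones leading in each case. Motif alternatives were not run. Unknown read totals limit what absence of a peak shows.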

Other observations

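The genes and neighbouring regions described here were singled out after their values had been seen, and the test across states was chosen at the same stage.

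Several genes held many called regions after stimulation, most of them long genes with many regions to call. Gained regions were most numerous at Slco3a1, an organic anion transporter gene, with 8 of 24 regions gained and 1 lost. All 4 regions assigned to Bicdl2 were gained (chromosome 17, gene from 23644605 to 23668621). Losses were most numerous at Nedd4l, a ubiquitin ligase gene, with 10 of 40 regions lost and 2 gained, and at Rptor, the gene of the scaffold of mTOR complex signalling, with 10 of 30 lost and 1 gained. At Ctnnd1, a catenin gene of cell adhesion, 7 of 14 regions were lost and 1 was gained. Myo10 held one of the leading lost regions, yet gained 5 regions and lost 2.

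Most neighbouring called regions moved the same way, and some moved in opposite directions. Of 129 pairs of called regions at most 1000 bp apart, 37 were gained together, 60 were lost together and 32 (24.8%) went opposite ways. No expected share was computed, and pairs drawn at random from 2868 gained and 5901 lost regions would also often differ in direction. Within Nfkb1, a gained region found in 9 stimulated and 0 unstimulated libraries (135602136 to 135602664) lay 32 bp from a lost region found in 0 and 12 (135602697 to 135603299). Within Srgn, the gene of the granule proteoglycan serglycin, a lost region found in 1 stimulated and 12 unstimulated libraries (chromosome 10, 62500202 to 62500521) lay 342 bp from a gained region found in 12 and 1 (62500864 to 62501462). Within Vash1 the gap was 479 bp, within Tenm4 545 bp and within Tbl1xr1 845 bp.

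If diabetes left a mark on chromatin that stimulation does not erase, differences between phenotypes before and after stimulation would go together across regions. Across regions with lists of equal length, the Pearson correlation of the differences was 0.0253. As large a value arose in 18 of 100 relabellings of the stimulated libraries (highest other 0.0626). The data therefore do not decide this hypothesis, and regions are not independent replicates.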
